A study of Mus musculus with 6 samples.

How the data were processed

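Bulk poly(A) RNA-seq was measured in cells derived from mouse embryonic stem cells, 3 samples from Ts1Cje and 3 from wild-type mice, all taken on day 4 of differentiation toward primitive macrophage progenitors, which are the earliest blood cells able to give rise to macrophages. Ts1Cje is a mouse model of Down syndrome that carries an extra copy of a distal part of chromosome 16. Per the labels' protocols, the stem cells were kept with LIF and serum replacement, the differentiation medium held FGF2, BMP-4, activin A and VEGF, and libraries were built with a poly(A) selection module and a directional kit.

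The authors deposited raw read counts per Ensembl gene and, in a separate table, TPM values for the same genes and libraries. Per the submitters' processing notes, the tools named are FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0 and featureCounts 1.6.3 with the mm10 genome; their order and settings, the counting strand and the handling of reads with several alignments are not given in the sources used here. Reads from overlapping or antisense genes therefore cannot be assigned to 1 of them with certainty. For the 11997 genes with over 50 counts in every library, the ratio of count to deposited TPM was scaled by the library's median. This ratio was the same across libraries for each gene, within a tolerance of 0.001 in 100% of values. The TPM summed to 1000000 per library. Gene lengths were not used, so the lengths behind the TPM were not checked. Gene coordinates and ontology terms were taken from the deposited tables, on mm10; coordinates were identical to those of the reference annotation for 99.4% of the 55141 identifiers found in both.

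Counts were analysed in R 4.3.3. Groups and replicate numbers came from the labels, and every value column matched 1 sample. Genes were kept with edgeR 4.0.16's filterByExpr (minimum count 10, minimum total count 15), libraries were scaled with TMM, and genotypes were compared with edgeR's quasi-likelihood test (robust glmQLFit, no covariate) with Benjamini-Hochberg adjustment over all genes kept; the threshold was an adjusted p of 0.05. All adjusted p-values of single genes come from this test unless another is named. Fold changes are Ts1Cje over wild-type on the log2 scale, with their SE. The SE was derived from the quasi-likelihood test, as the absolute log2 fold change over the square root of F. It is therefore approximate. Expression levels are CPM with TMM scaling, given as mean ± SD over 3 libraries. Total counts ran from 16577065 to 19010856 per library. For a gene with 0 counts in a group, the fold is a lower bound against a floor of 3 counts over the group. For a gene with 1 to 3 counts in a group, the ratio of summed CPM is given with a 95% exact binomial interval. Both pool the counts of a group's 3 libraries and cover counting error only, not the spread between libraries. The reads carry no molecular identifiers, so even counting error may be understated.

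The triplicated segment was taken as chromosome 16 (mm10) from position 90225680, where the next gene after the start of Sod1 begins and overlaps its end, to 97962622, the end of Zbtb21. Its dosage was the median over its tested genes of the log2 CPM minus the wild-type mean in each library. The 6 library values were compared with a 2-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Deviation of single genes from 1.5-fold was tested by adding that factor to the offset of the Ts1Cje libraries, with adjustment over the segment's tested genes. The same dosage measure was taken over a list of genes at the deletion on chromosome 12 that Ts1Cje is known to carry.

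Gene lists were fixed for the triplicated segment, the chromosome 12 deletion, pluripotency, primed epiblast, primitive streak and early mesoderm, lateral and extraembryonic mesoderm, cardiac mesoderm, hemogenic endothelium and blood vessel, blood progenitor, primitive erythroid, macrophage and myeloid, megakaryocyte, definitive and visceral endoderm, neuroectoderm, trophoblast, fibroblast and feeder, type I interferon response, p53 targets, NRF2 targets, integrated stress response, hypoxia and glycolysis, cell cycle, VEGF and FGF signalling feedback, BMP and activin signalling feedback, WNT targets, Hox genes, imprinted genes, Y chromosome, X inactivation, mitochondrial genome, replication-dependent histones, and dissociation and immediate early genes. The lists, the tests, most alternatives and the rule for naming genes were chosen before the data were examined. Of the 32 lists, 30 had at least 5 tested genes and were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the lists; triplicated genes were left out of every other list. Camera with an estimated correlation and fry were run beside it. Ontology terms with 10 to 500 tested genes were tested with camera in the same way. Among the alternatives below, DESeq2 results were tested with the preranked form of camera on Wald statistics. With limma-voom, camera used the voom weights. In both, the set test thus changed together with the test of single genes.

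The genes named are those with the 10 largest changes in each direction (adjusted p below 0.05, mean log2 CPM of at least 1, no overlap between the groups' libraries, triplicated genes and gene models without a symbol of their own left out), up to 4 passing members of each list by smallest adjusted p, the triplicated genes with the 6 smallest adjusted p, those that fell and up to 6 that differ from 1.5-fold, and a fixed set (Sod1, Erg, Runx1, Ets2, Dyrk1a, Ifnar1, Ifnar2, Kdr, Etv2, Tal1, Spi1, Csf1r, Gata1, Hbb-bh1, Pou5f1, T, Xist and Ddx3y). Any other gene named was chosen after its values were seen. Some genes that the rule names are not reported here.

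Medians of log2 fold changes were taken per chromosome and per 10 Mb window with at least 20 tested genes. After shifted windows had been seen, the position of the step on each chromosome was located with a scan that required at least 20 genes on each side and a step of at least 0.3, and was compared with 1000 shuffles of gene order.

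The steps were tested on simulated counts for 16981 genes, drawn from the means, spread and library sizes of this comparison. Of the genes changed by a known factor, the test recovered 47.0% at 1.5-fold (31 of 66), 67.7% at 2-fold (44 of 65) and 92.3% at 4-fold (60 of 65), and 23 of 16692 unchanged genes passed, which was 10.4% of the genes that passed and above the threshold of 0.05. Of 66 simulated triplicated genes set at 1.5-fold, 0 were called different from 1.5-fold, and 6 of 10 left unchanged were called below it. Both of the 2 lists changed in the simulation passed, and 0 unchanged lists did. In the simulation, genes changed by 1.5-fold were thus often missed. It left most genes unchanged, whereas many more passed in the real comparison, so its adjusted threshold required a smaller unadjusted p. These shares therefore do not carry over to the real comparison.

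Alternatives were DESeq2 1.42.0, DESeq2 size factors or upper-quartile factors in edgeR, no filter on low counts, a minimum mean log2 CPM of 1, the replicate number as a block, limma-voom, limma-trend on log2 of the deposited TPM plus 1 or plus 0.1 (TPM of at least 1 in 3 libraries), leaving out each library in turn, stricter thresholds, and, chosen after seeing the data, leaving out shifted chromosome segments.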

Results

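Gene expression was measured in 6 libraries of cells grown from mouse embryonic stem cells for 4 days toward primitive macrophage progenitors, 3 labelled Ts1Cje and 3 labelled wild-type. The comparison asks how the extra distal part of chromosome 16 in this Down syndrome model goes with gene expression at the stage where yolk-sac type blood cells begin to form. Wild-type libraries held 18459721, 18587516 and 18513795 counts and Ts1Cje libraries 18320582, 16577065 and 19010856. Of 55487 genes in the table, 17315 were tested, 13814 of them protein-coding. The first principal component held 79.1% of the variance and separated the genotypes. On it, wild-type replicate 1 lay nearer to Ts1Cje than the other wild-type libraries did (−50.0 against −72.4 and −73.0). On the next, with 8.31%, wild-type replicate 1 also stood apart from the other wild-type libraries (39.4 against −9.83 and −23.7). Correlations of log2 CPM across genes were 0.980 to 0.989 within wild-type, 0.986 to 0.987 within Ts1Cje and 0.912 to 0.943 between genotypes. Replicate pairs differed by more than sampling noise (chi-square over degrees of freedom 4.53 to 16.8). The labels number the samples by lot and do not say that lots are separate cultures or lines, so p-values measure the spread between these samples, which may be technical. Genotype and the cell lines it came from also cannot be separated.

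Genes of the triplicated segment (mm10, chromosome 16, 90225680 to 97962622, 7.74 Mb) were mostly higher in Ts1Cje. Of 76 tested genes, 48 rose, 6 fell and 22 did not pass, and adjusted over the list alone 49 rose and 6 fell. Their median log2 fold change was 0.48, or 1.39-fold (quartiles 0.20 and 0.82), and 0.50 over the 56 protein-coding genes. Per library, the segment's median deviation from the wild-type mean was 0.49 ± 0.03 in Ts1Cje and 0.00 ± 0.01 in wild-type (SD, n = 3 each; exact permutation test, p = 0.1, the smallest this design allows). The 426 tested genes of chromosome 16 that lie before Sod1 had a median of −0.03. The list also passed camera at the preset correlation (adjusted p = 1.77e-07) and with an estimated correlation (adjusted p = 0.0497).

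The segment's smallest adjusted p-values belonged to Ripk4, a kinase of epidermal differentiation (log2 fold change 2.38 ± 0.09 SE, adjusted p = 4.1e-07), Rcan1, an inhibitor of calcineurin (1.74 ± 0.08), Synj1, a phosphoinositide phosphatase of endocytosis (1.88 ± 0.11), Tmprss2, a membrane serine protease (3.50 ± 0.18), Cfap298, a cilium protein gene (1.21 ± 0.10), and Gart, an enzyme of purine synthesis (0.80 ± 0.07). Runx1, the transcription factor needed for blood formation from endothelium, rose from 7.70 ± 0.62 to 26.8 ± 11.8 CPM (SD, n = 3 each; 1.80 ± 0.29, adjusted p = 0.00188). Dyrk1a, a kinase gene often studied in Down syndrome, rose by a log2 value of 0.33 ± 0.06. Erg, an endothelial and blood stem cell transcription factor (chromosome 16, 95359169 to 95586593, minus strand), fell from 6.49 ± 2.5 to 0.485 ± 0.097 CPM (log2 fold change −3.73 ± 0.39, adjusted p = 5.63e-05). The potassium channel genes Kcnj6 (−1.88 ± 0.47) and Kcnj15 (−2.15 ± 0.68), the kinase gene Hunk (−0.25 ± 0.09) and the transcripts Gm49708 (−1.19 ± 0.21) and Gm49709 (−1.05 ± 0.38) fell as well. The interferon receptor gene Ifnar1 rose by 0.30 ± 0.09 and the transcription factor gene Ets2 by 0.29 ± 0.10, while Ifnar2 stood at −0.04 ± 0.15 (adjusted p = 0.862). Sod1, at the edge of the segment and not counted in it, is known as disrupted on the extra copy in this model, but in these counts it rose by 0.83 ± 0.06, or 1.78-fold.

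**Figure D1:**
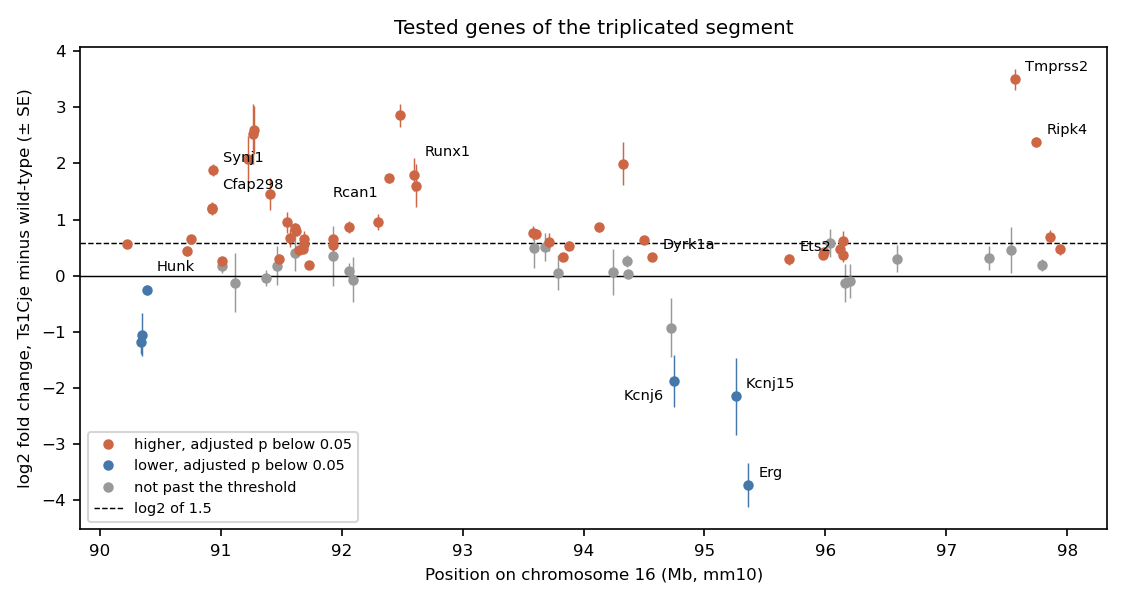
Log2 fold change (Ts1Cje minus wild-type, ± SE, n = 3 libraries per group) of the 76 tested genes of the triplicated segment against their start on chromosome 16 in Mb (mm10), with the dashed line at log2 of 1.5. Of these genes 48 rose, 6 fell and 22 did not pass, and Erg lies lowest at −3.73.

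Several of these calls in the segment were lost on leaving out single libraries or with another test or filter. Hunk lost its call on leaving out wild-type replicate 1, 2 or 3 or Ts1Cje replicate 1 or 3 (adjusted p = 0.0549 to 0.157), Ets2 on leaving out wild-type replicate 1, 2 or 3 or Ts1Cje replicate 2 or 3 (0.0609 to 0.156), Ifnar1 on leaving out wild-type replicate 2 or Ts1Cje replicate 2 or 3 (0.0622 to 0.0822), Kcnj15 on leaving out wild-type replicate 1 or any Ts1Cje library (0.0712 to 0.117) and Gm49709 on leaving out wild-type replicate 1 or 2 or Ts1Cje replicate 2 or 3 (0.0989 to 0.143). With all 6 libraries, Ets2 was also lost with DESeq2 (0.0549), upper-quartile factors (0.0522) and limma-trend on TPM (0.0730 and 0.0734), Hunk with limma-trend (0.118 in both fits) and a minimum mean log2 CPM of 1 (0.0507), Kcnj15 with limma-voom (0.105) and Gm49709 with DESeq2 (0.0618). Without wild-type replicate 1, or without Ts1Cje replicate 3, 3 segment genes fell in place of 6.

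Of the 76 triplicated genes, 38 differed from 1.5-fold (edgeR's quasi-likelihood test against that factor, adjusted p below 0.05 over the segment), 18 above and 20 below it, and 12 of the 20 still had a log2 fold change above 0. Ripk4, Tmprss2, Rcan1 and Synj1 lay above 1.5-fold, by log2 values of 1.80, 2.92, 1.15 and 1.29. Erg, Hunk, Kcnj6, Dyrk1a (−0.26) and Ifnar2 (−0.62) lay below. The remaining 38 were not told apart from 1.5-fold. Outside the segment, 3984 of 17239 tested genes rose and 3541 fell, tested against no change and adjusted over all genes. Changes of single genes were thus common there too, so the deviations from 1.5-fold need not concern the segment's dosage. The count fell to 21 without wild-type replicate 2 and 23 without Ts1Cje replicate 1.

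Ts1Cje is known to carry a deletion on chromosome 12, and 5 genes of the list fixed for it were tested. A deletion lowers the copy number of its genes. In these libraries 2 genes of the list were lower, Itgb8 and Sp4, the latter the next coding gene after Dnah11 toward the chromosome end. The list as a whole was not lower, and these values do not tell where the borders of the deletion lie. They also do not tell whether either fall came from a lost copy, and Itgb8 fell further than the loss of 1 of 2 copies alone would give. Dnah11, a heavy chain of ciliary dynein (ENSMUSG00000018581, chromosome 12, 117877982 to 118199043, minus strand), rose from 16.4 ± 3.05 to 753 ± 26.9 CPM (SD, n = 3 each), a log2 fold change of 5.52 ± 0.13 with an adjusted p of 9.96e-08, the smallest of all genes tested. Cdca7l, a MYC-interacting factor that shares 725 bp with Dnah11, rose (0.78 ± 0.09), whereas Itgb8, an integrin subunit (−4.02 ± 0.40), and Sp4, a zinc finger transcription factor (−1.39 ± 0.15), fell. Since the counting strand is not stated, reads in the part shared by Dnah11 and Cdca7l are uncertain. Of the list, 2 genes rose, 2 fell and 1 did not pass, and adjusted over the list alone 3 rose and 2 fell. The list's median was 0.72. Its library median was 0.59 ± 0.31 in Ts1Cje and −0.02 ± 0.18 in wild-type (SD, n = 3; exact permutation test, p = 0.1), and camera gave an adjusted p of 0.744, against 1.9e-05 when run on DESeq2 results; fry gave 0.00167.

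Across all genes, 7579 of 17315 (43.8%) differed between the genotypes, 4032 higher and 3547 lower in Ts1Cje, and 3128 of them by at least 2-fold (2018 higher, 1110 lower). In 55.2% of tested genes the groups' libraries did not overlap, where chance gives 10%. The largest increases were those of Foxd4, a forkhead factor (380 counts against 2, a ratio of 194, 95% interval 53.3 to 1607), Cer1, a secreted NODAL and BMP antagonist of anterior endoderm (1.05 ± 0.57 to 125 ± 47.7 CPM, log2 fold change 6.88 ± 0.53), the fatty acid transporter gene Slc27a2 (6.46 ± 0.39), Depp1 (ratio 96.3, 95% interval 32.6 to 469.6), the cytoskeletal gene Ermn (ratio 75.2, 95% interval 25.4 to 367), the calcitonin gene Calca (5.80 ± 0.38), the forebrain factor gene Six3 (5.56 ± 0.80), Dnah11, the epiblast growth factor gene Fgf5 (4.00 ± 3.25 to 183 ± 6.66 CPM, 5.51 ± 0.49) and Foxd3, a factor of epiblast and neural crest (5.43 ± 0.31).

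The largest decreases included several Hox genes. Hoxc8 had 220 counts in wild-type and 0 in Ts1Cje, at least 71.9-fold lower against 3 counts over the group. Cdx4, a caudal factor upstream of Hox genes, had 704 counts against 1 (ratio 690, 95% interval 123 to 27285). The ratios were 570 for Hoxb6 (95% interval 102 to 22563), 202 for Hoxb8 (68.9 to 983), 190 for Sox18, an endothelial factor (52.3 to 1575), and 113 for the GABA transporter gene Slc32a1 (31.0 to 940.1). Hoxd9 (−6.57 ± 0.57), Hoxd8 (−5.45 ± 0.67), the collagen gene Col1a1 (−6.55 ± 1.27) and Hlx, a mesoderm homeobox gene (−5.51 ± 0.97), completed the group. Col1a1 lost its call with limma-voom (adjusted p = 0.213) and without Ts1Cje replicate 1 (0.0589) or 3 (0.0532), and Hlx with limma-voom (0.0519). Sox18 lies in a stretch of chromosome 2 whose genes were mostly lower.

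Genes of pluripotency, primed epiblast and endoderm were higher in Ts1Cje. Of 18 tested pluripotency genes 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median log2 fold change of 1.83. Tfcp2l1 (6.10 ± 1.44 to 28.1 ± 5.29 CPM), Klf5 (2.33 ± 0.21) and Zfp42 (2.53 ± 0.30), factors of the naive stem cell state, rose, and Tbx3 fell (143 ± 11.5 to 49.4 ± 9.59 CPM). Klf5 lies in a segment of chromosome 14 whose genes were mostly higher. Pou5f1, which encodes OCT4, stood at 61.8 ± 55.2 CPM in wild-type and 343 ± 111 in Ts1Cje (2.47 ± 0.71, adjusted p = 0.0415) and lost its call without wild-type replicate 2 (0.0921) or 3 (0.080) or Ts1Cje replicate 1 (0.122), 2 (0.0749) or 3 (0.0942). The list passed camera (adjusted p = 0.000418; adjusted p = 0.590 with an estimated correlation). In primed epiblast, the state of the embryo just before gastrulation, 6 of 9 genes rose and 2 fell, with the same counts adjusted over the list alone and a median of 1.98. Without wild-type replicate 2 or 3 or Ts1Cje replicate 2 or 3, or with limma-trend on TPM, 1 fell. Besides Fgf5, Otx2 (10.4 ± 4.33 to 139 ± 17.3 CPM), Sox3 (2.93 ± 0.38) and the DNA methyltransferase gene Dnmt3b (1.98 ± 0.21) rose (camera adjusted p = 0.0233; adjusted p = 0.631 with an estimated correlation).

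Definitive and visceral endoderm had 15 of 18 genes higher and 1 lower (16 and 1 adjusted over the list alone; 2 lower without Ts1Cje replicate 2 or with no filter), with a median log2 fold change of 2.38. Sox17, a master factor of endoderm, rose from 21.4 ± 1.78 to 194 ± 29.1 CPM (3.18 ± 0.12, adjusted p = 6.9e-07), Foxa2 from 5.68 ± 2.12 to 121 ± 15.2 CPM (4.41 ± 0.24), the liver and visceral endoderm factor Hnf4a by 2.83 ± 0.20 and Rhox5 by 2.75 ± 0.17. Camera gave an adjusted p of 9.4e-06 for this list (adjusted p = 0.341 with an estimated correlation).

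**Figure D2:**
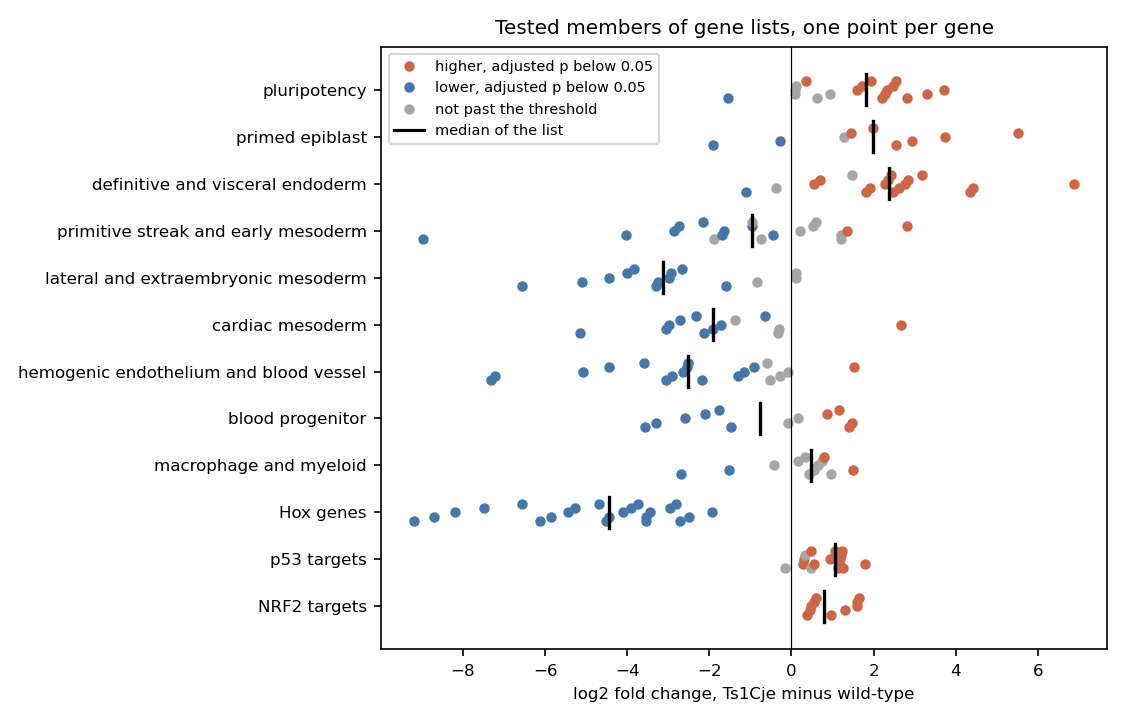
Log2 fold change (Ts1Cje minus wild-type, 3 libraries per group) of each tested member of 12 gene lists, coloured by whether it passed the test, with a bar at the list's median. The medians run from −4.44 for Hox genes to 2.38 for endoderm.

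Mesoderm, vessel and Hox genes were lower. In lateral and extraembryonic mesoderm, which gives rise to yolk sac and body wall, 11 of 14 genes fell and 0 rose, with the same counts adjusted over the list alone and a median of −3.12; 1 rose without wild-type replicate 1. The growth factor gene Bmp4 fell from 211 ± 44.7 to 9.82 ± 4.61 CPM (−4.43 ± 0.37), and the homeobox genes Msx1 (−3.26 ± 0.27) and Msx2 (−2.66 ± 0.17) and Bmper, a BMP-binding protein gene (−1.60 ± 0.14), fell (camera adjusted p = 1.1e-05; adjusted p = 0.341 with an estimated correlation). Of 13 cardiac mesoderm genes 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of −1.91. Gata5 (−5.16 ± 0.53), Mef2c (−2.70 ± 0.38), the troponin gene Tnni1 (−2.33 ± 0.24) and the actin gene Actc1 (−1.71 ± 0.27) fell (camera adjusted p = 0.00124; adjusted p = 0.341 with an estimated correlation). Gata5 lies in the same stretch of chromosome 2 as Sox18.

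Of 19 genes of hemogenic endothelium and blood vessel, the tissue from which the first blood cells arise, 14 fell and 1 rose, with the same counts adjusted over the list alone and a median of −2.52. Kdr, the VEGF receptor that marks blood and vessel precursors, fell from 442 ± 26.5 to 70.5 ± 35.8 CPM (−2.65 ± 0.41, adjusted p = 0.00478), and Etv2, the factor that starts that lineage, from 44.2 ± 11.9 to 7.74 ± 3.86 CPM (−2.52 ± 0.44, adjusted p = 0.00539). Fli1 (−4.44 ± 0.31) and Lmo2 (−2.90 ± 0.29) fell, Icam2 was at least 18.3-fold lower (56 counts against 0), and the VEGF receptor gene Flt1 rose from 58.9 ± 3.76 to 168 ± 3.31 CPM (1.51 ± 0.07). Camera gave an adjusted p of 1.9e-05 (adjusted p = 0.341 with an estimated correlation), and the median did not change with Icam2 at its bound.

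All 23 tested Hox genes, which pattern the body axis, fell, with the same count adjusted over the list alone. Their median was −4.44, also with Hoxc8 and Hoxd3 (at least 36.3-fold lower, 111 counts against 0) at their bounds. Hoxa3 fell by 4.09 on the log2 scale (SE 0.47, n = 3 per group), and Hoxb5 had a ratio of 82.3 (95% interval 22.4 to 685). Camera gave an adjusted p of 5.4e-11 (adjusted p = 0.341 with an estimated correlation). All 23 also fell with DESeq2 size factors or upper-quartile factors in edgeR, 22 of 23 with limma-voom and without wild-type replicate 2, 24 of 25 tested with DESeq2, 19 of 20 with limma-trend on TPM and 23 of 25 on leaving out any 1 of the Ts1Cje libraries. With limma-trend on log2(TPM + 1) the median was −2.29.

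Blood genes went both ways. Of 12 blood progenitor genes, 4 rose and 6 fell, with the same counts adjusted over the list alone and a median of −0.77 (−1.76 without wild-type replicate 1, −1.16, −1.20 and −1.47 without Ts1Cje replicates 1, 2 and 3, and −0.06 with limma-trend on log2(TPM + 1); camera adjusted p = 0.457). Tal1, the master factor of blood commitment, fell from 81.4 ± 12.2 to 6.97 ± 3.96 CPM (−3.56 ± 0.39, adjusted p = 0.000912), Gata2 from 29.1 ± 7.25 to 4.87 ± 1.31 CPM, and the integrin gene Itga2b from 9.31 ± 3.20 to 2.74 ± 0.39 CPM, while Hhex, a factor of both blood and endoderm, rose (1.15 ± 0.17). Of 7 primitive erythroid genes, 3 rose and 1 fell, the same adjusted over the list alone (median 0.25, camera adjusted p = 0.612). This median was 0.47, 0.65 and −0.22 without wild-type replicates 1, 2 and 3, 0.19, 0.56 and −0.07 without Ts1Cje replicates 1, 2 and 3, and 2.34 with a minimum mean log2 CPM of 1. Fry gave an adjusted p of 0.0145, and without Ts1Cje replicate 1, 0 genes of the list fell in edgeR's quasi-likelihood test. Gata1 rose from 0.506 ± 0.242 to 3.53 ± 1.68 CPM and the carbonic anhydrase gene Car2 from 38.0 ± 8.76 to 140.2 ± 4.95 CPM. The embryonic globin gene Hbb-bh1 had 3 counts over wild-type and 0 over Ts1Cje and was not tested.

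Most macrophage genes had too few counts to be tested, and those tested went both ways. Of 27 macrophage and myeloid genes 12 were tested, and 2 rose and 2 fell (1 and 2 adjusted over the list alone; 1 rose without wild-type replicate 2 or Ts1Cje replicate 2), with a median of 0.48 (camera adjusted p = 0.396). Csf1r, the macrophage growth factor receptor, stood at 14.3 ± 1.46 CPM in wild-type and 18.1 ± 2.12 in Ts1Cje (0.34 ± 0.14, adjusted p = 0.0703) and passed without wild-type replicate 1 (0.0301). The lysosomal gene Laptm5 rose from 0.761 ± 0.059 to 2.15 ± 0.63 CPM. Spi1, which encodes the myeloid factor PU.1, had 3, 0 and 6 counts in wild-type and 5, 3 and 3 in Ts1Cje and was not tested. Of 3 megakaryocyte genes 2 fell, the same adjusted over the list alone, and the list was too short for camera. They were Itgb3 (−1.50 ± 0.44), whose call was lost without wild-type replicate 2 (0.0698) or Ts1Cje replicate 1 (0.0728) or 2 (0.0545), and Gp1ba (−1.27 ± 0.42), without wild-type replicate 1 (0.097) or Ts1Cje replicate 1 (0.0746) or 3 (0.103). With limma-trend on TPM the 1 megakaryocyte gene tested did not pass, and 1 rose on leaving out any 1 of the wild-type libraries or Ts1Cje replicate 1, when 4 were tested.

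**Figure D3:**
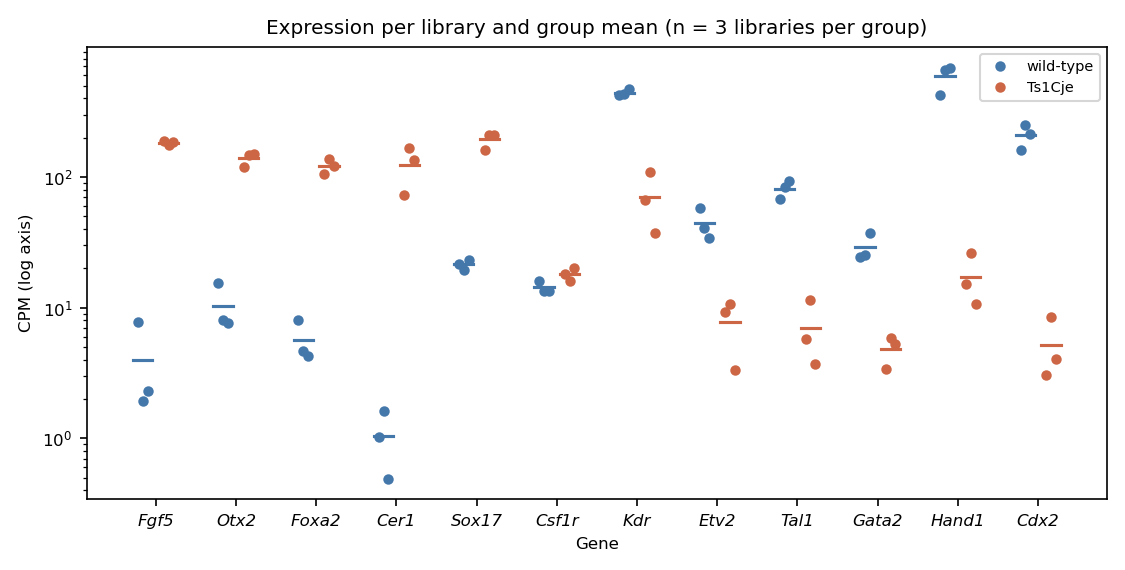
CPM of 12 genes in each library on a log axis, with a bar at each group's mean (n = 3 libraries per group). Fgf5, Otx2, Foxa2, Cer1 and Sox17 were higher in every Ts1Cje library, Kdr, Etv2, Tal1, Gata2, Hand1 and Cdx2 lower, and Csf1r differed little (14.3 and 18.1 CPM).

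Genes of primitive streak and early mesoderm, the tissue of gastrulation, also split. Of 19 genes, 2 rose and 9 fell (3 and 9 adjusted over the list alone), with a median of −0.96 (camera adjusted p = 0.119). Gsc, a factor of the anterior streak and organizer, rose (4.11 ± 1.42 to 28.9 ± 2.86 CPM), while Cdx1 (−2.75 ± 0.59) and Fgf8 (−0.45 ± 0.10) fell. T, or brachyury, stood at 233 ± 116 CPM in wild-type and 139 ± 26.0 in Ts1Cje (adjusted p = 0.183). The list passed camera when wild-type replicate 3 was left out (0.0286) and with no filter on low counts (0.0432). It did not pass with an estimated correlation (adjusted p = 0.841), and fry gave an adjusted p of 0.142. Without wild-type replicate 1, 6 genes rose, 8 fell and the median was −0.37, and without Ts1Cje replicate 1, 1 rose and 5 fell; 1 rose on leaving out any other library.

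Markers of other cell types the cultures could hold were measured too. Of 6 neuroectoderm genes 1 rose, Sox21 (3.24 ± 0.27), which lies in the same segment of chromosome 14 as Klf5, and 2 fell, Pax3 (−2.48 ± 0.53) among them, the same adjusted over the list alone (median −0.33, camera adjusted p = 0.915). Over the alternatives the neuroectoderm median ran from −0.78 without wild-type replicate 3 to 0.38 with a minimum mean log2 CPM of 1, and it was 0.03 without Ts1Cje replicate 2; 3 genes rose without wild-type replicate 1. In this list 1 gene fell without Ts1Cje replicate 1 or 3 or with limma-voom, and 0 with limma-trend on TPM. Of 9 trophoblast genes 4 rose and 3 fell, the same adjusted over the list alone; the median was 0.05 (from −0.17 without Ts1Cje replicate 3 and −0.09 without Ts1Cje replicate 2 to 0.18 without wild-type replicate 1, 0.35 without Ts1Cje replicate 1 and 1.27 with no filter), the mean −0.76 and the camera direction up (adjusted p = 0.988). Cdx2 fell from 208 ± 44.5 to 5.21 ± 2.91 CPM and Hand1, also a mesoderm factor, from 589 ± 146 to 17.3 ± 7.93 CPM, and the keratin gene Krt7 rose (2.90 ± 0.37). Of 11 fibroblast and feeder genes 9 fell and 0 rose, the same adjusted over the list alone (median −1.52, camera adjusted p = 0.000418; adjusted p = 0.223 with an estimated correlation). They include the actin gene Acta2 (14.1 ± 4.90 to 1.77 ± 0.84 CPM), Tagln (−1.32 ± 0.18), the collagen gene Col5a1 (130.5 ± 35.1 to 29.9 ± 5.24 CPM) and Fbln2 (−2.14 ± 0.28).

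Stress genes under p53 and NRF2 were higher. Of 17 p53 targets 14 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 1.07. The cell cycle inhibitor gene Cdkn1a rose from 34.6 ± 4.32 to 81.8 ± 4.19 CPM (1.24 ± 0.10), and Trp53inp1 (1.24 ± 0.07), Phlda3 (1.07 ± 0.09) and Btg2 (1.20 ± 0.11) rose alike (camera adjusted p = 1.1e-05; adjusted p = 0.223 with an estimated correlation). All 10 NRF2 targets, genes of the antioxidant response, rose, the same adjusted over the list alone, with a median of 0.78. The catalase gene Cat rose from 103 ± 4.72 to 201 ± 16.3 CPM, and Gclm (1.59 ± 0.12), Hmox1 (1.30 ± 0.13) and Srxn1 (1.63 ± 0.22) rose (camera adjusted p = 0.000138; adjusted p = 0.498 with an estimated correlation). Of 28 cell cycle genes 16 fell and 1 rose (16 and 2 adjusted over the list alone; 2 rose without wild-type replicate 1), with a smaller median of −0.21; the replication helicase genes Mcm3 (−0.52 ± 0.06) and Mcm6 (−0.52 ± 0.06), Top2a (−0.41 ± 0.05) and the spindle checkpoint gene Bub1 (−0.46 ± 0.06) fell (camera adjusted p = 0.00253; adjusted p = 0.341 with an estimated correlation).

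Feedback genes of the BMP, activin, VEGF and FGF pathways and targets of WNT signalling gave mixed results. Of 13 genes that report BMP and activin signalling, 3 rose and 7 fell (3 and 8 adjusted over the list alone), with a median of −0.78. Bambi fell from 91.2 ± 12.7 to 22.4 ± 3.39 CPM, Id2 from 52.0 ± 6.12 to 19.6 ± 2.82 CPM and Atoh8 from 6.42 ± 1.48 to 1.10 ± 0.60 CPM. Camera gave an adjusted p of 0.0662, which passed with DESeq2 (0.00225), no filter (0.0199) and limma-voom (0.0451) and without wild-type replicate 2 (0.0395) or 3 (0.0492) or Ts1Cje replicate 1 (0.0418), but not with an estimated correlation (adjusted p = 0.341); fry gave 0.000889. Without wild-type replicate 3, 1 of these genes rose in place of 3. Of 13 WNT targets 2 rose and 8 fell, the same adjusted over the list alone, with a median of −1.11. Notum (−2.66 ± 0.32), Nkd1 (−2.31 ± 0.33), Tcf7 (−0.66 ± 0.09) and Ccnd1 (−1.11 ± 0.19) fell. Ccnd1 lies in a segment of chromosome 7 whose genes were mostly lower. Camera gave an adjusted p of 0.0636, which passed with DESeq2 (0.0115), no filter (0.0167) and limma-voom (0.0365) and without wild-type replicate 2 (0.0395) or 3 (0.0286) or Ts1Cje replicate 2 (0.0348) or 3 (0.0486), but not with an estimated correlation (adjusted p = 0.722); fry gave 0.0435. Of 14 genes that report VEGF and FGF signalling, 1 rose and 4 fell, the same adjusted over the list alone (median −0.36, or −0.19 without Ts1Cje replicate 3; camera adjusted p = 0.149). Il17rd (−0.73 ± 0.09), Spred1 (−0.71 ± 0.09) and Spred2 (−0.43 ± 0.10) fell and Etv4 rose (0.77 ± 0.18).

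Other responses showed no common direction. Of 19 type I interferon response genes, 6 rose and 3 fell, the same adjusted over the list alone, with a median of −0.00096 (0.30 without wild-type replicate 1), a mean of 0.15 and the camera direction up (adjusted p = 0.620). Trim25 (1.23 ± 0.08), Ddx58 (1.26 ± 0.18) and Xaf1 (2.84 ± 0.42) rose, and the immunoproteasome gene Psmb8 fell from 10.8 ± 0.59 to 1.15 ± 0.41 CPM. Of 15 integrated stress response genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.01, from −0.06 without wild-type replicate 2 to 0.42 without wild-type replicate 1; 1 fell without wild-type replicate 3 or Ts1Cje replicate 1 or with limma-trend on TPM; camera adjusted p = 0.579). Phgdh (1.01 ± 0.13), Sesn2 (0.95 ± 0.16) and Slc3a2 (0.42 ± 0.08) rose and the lipoprotein receptor gene Vldlr fell (−2.01 ± 0.10). Of 20 hypoxia and glycolysis genes, 5 rose and 8 fell, the same adjusted over the list alone, with a median of −0.35, a mean of 0.03 and the camera direction down (adjusted p = 0.396). Ndrg1 rose (1.95 ± 0.10), and Ldha (−0.48 ± 0.07), Pfkp (−1.89 ± 0.22) and Egln3 (−0.98 ± 0.13) fell. Of 13 dissociation and immediate early genes, 3 rose and 1 fell (2 and 1 adjusted over the list alone; median 0.12, but −0.15 without wild-type replicate 3 and −0.12 without Ts1Cje replicate 1; camera adjusted p = 0.988; 2 rose and 4 fell without Ts1Cje replicate 2, and 3 and 5 with the replicate block, whereas 0 fell in edgeR's quasi-likelihood test without wild-type replicate 1 or 2 or Ts1Cje replicate 1 or 3, or with limma-trend on TPM), with Atf3 (1.12 ± 0.23) and Zfp36 (0.60 ± 0.15) among those higher.

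Lists that can tell cell lines apart were included. Of 26 imprinted genes, 4 rose and 14 fell (4 and 16 adjusted over the list alone), with a median of −0.67 (camera adjusted p = 0.00566; adjusted p = 0.590 with an estimated correlation). Peg10 fell from 2325 ± 209.7 to 919 ± 144 CPM, Peg3 (−0.66 ± 0.06) and Usp29 (−0.81 ± 0.09) fell, and Snrpn rose (1.15 ± 0.12). Of 5 Y chromosome genes 1 rose (0 adjusted over the list alone; median 0.10, camera adjusted p = 0.754). It was Ddx3y, at 48.7 ± 6.10 CPM in wild-type and 62.1 ± 6.12 in Ts1Cje, which lost its call without wild-type replicate 3 (0.101) or Ts1Cje replicate 1 (0.090) or 3 (0.0983). Of 4 genes of the X inactivation centre 3 rose, the same adjusted over the list alone, with a median of 0.95 and too few genes for camera; with limma-trend on TPM 1 rose, and 2 rose with limma-voom, upper-quartile factors or on leaving out any library other than Ts1Cje replicate 2. The call lost was that of Ftx (adjusted p = 0.0663 to 0.184 on leaving out a library). Xist stood at 1.74 ± 0.08 CPM in wild-type and 4.51 ± 0.91 in Ts1Cje, and Tsix at 0.76 ± 0.23 and 3.62 ± 0.38; these genes overlap on opposite strands, so which of them the reads belong to is uncertain. Of 12 mitochondrial genes 4 rose, the same adjusted over the list alone (median 0.28, camera adjusted p = 0.207), with mt-Nd5 (0.30 ± 0.07) and mt-Nd6 (0.32 ± 0.08) among them; mitochondrial genes took 1.68, 1.66 and 1.52% of counts in the wild-type libraries and 2.09, 1.84 and 1.83% in Ts1Cje, with no overlap between the groups. Without wild-type replicate 2, 2 of them rose, with upper-quartile factors 3 rose and 1 fell, with no filter 7 rose and 1 fell, and the median was 0.14 without Ts1Cje replicate 1 and 0.18 without wild-type replicate 3. Of 20 replication-dependent histone genes, 7 were tested, and the values cover only transcripts that the poly(A) selection kept. Of these 7 genes 2 rose, H2bc4 (2.57 ± 0.23) and H1f2 (1.70 ± 0.26), the same adjusted over the list alone. The histone median was −0.07 (−0.43 without wild-type replicate 3 and 0.51 without wild-type replicate 1). Over all alternatives it ran from −0.48 with limma-trend on log2(TPM + 0.1) to 1.71 with a minimum mean log2 CPM of 1. The mean was 0.34 and the camera direction up (adjusted p = 0.809).

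Among the 30 lists tested, 13 passed camera at the preset correlation, 6 higher and 7 lower in Ts1Cje, and of these only the triplicated segment held with an estimated correlation. Fry, which asks whether the genes of a list move on balance one way, gave 17 lists, 8 higher and 9 lower.

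Gene ontology terms outside the triplicated segment covered further functions. Of 2663 terms, 57 passed camera, 22 higher and 35 lower, and 0 passed with an estimated correlation in camera (53 at an unadjusted p below 0.05; adjusted p = 0.786 for the terms named here). Higher in Ts1Cje was the term lysosome (211 genes, 104 rose and 22 fell, median 0.36, adjusted p = 0.000572), together with proton transmembrane transport (40 genes, 25 rose and 3 fell), lipid transport (77 genes, 40 and 7), glutathione metabolic process (32 genes, 21 and 2), brush border (38 genes, 23 and 6) and cilium movement (34 genes, 17 and 2, median 0.77). Lower were embryonic skeletal system morphogenesis (44 genes, 4 rose and 29 fell, median −2.08), anterior/posterior pattern specification (89 genes, 12 and 45), blood vessel development (48 genes, 5 and 27, median −0.94), definitive hemopoiesis (12 genes, 0 and 10, median −1.29), positive regulation of BMP signaling pathway (33 genes, 1 and 19), mRNA processing (217 genes, 8 and 70, median −0.14) and cytoplasmic translation (32 genes, 0 and 21, median −0.29).

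Chromosome medians of the log2 fold change ran from −0.09 to 0.09 over 20 chromosomes (autosomes and X), and the largest deviation of a single library from the others was 0.10. Of 240 windows of 10 Mb, 9 had a median beyond 0.3 in either direction. These lay on chromosomes 2 (1 window), 3 (2), 8 (2), 16 (1), 14 (0.54), 4 (0.34) and 12 (−0.33). Once they had been seen, a scan for a step along each chromosome was made, and it located segments at the ends of chromosomes 2, 3, 7, 8, 11, 14 and 16. On chromosome 8, the 195 tested genes from Dhx38 to the end (109548011 to 129282844) had a median of 0.50, or 1.42-fold, and 123 rose and 10 fell. On chromosome 3, the 80 genes from 141457976 to 159938664 had a median of −0.66, and 7 rose and 49 fell. On chromosome 2, the 65 genes from 177759288 to 181870830 had a median of −0.74, and 7 rose and 38 fell. Their library medians were 0.49 ± 0.05, −0.62 ± 0.08 and −0.75 ± 0.07 in Ts1Cje and 0.00 ± 0.02, 0.00 ± 0.01 and 0.00 ± 0.02 in wild-type (SD, n = 3 each; exact permutation test, p = 0.1 for each). The scan gave 0.000999 for each, the smallest p that 1000 shuffles can give. The segment on chromosome 7, 45 genes from 142283210 to 145284011, had a median of −0.86, and 5 rose and 23 fell, with a library median of −0.77 ± 0.06 in Ts1Cje (permutation p of the scan = 0.000999). On chromosome 14, 65 genes from 99075206 to 124677127 had a median of 0.42, and 34 rose and 7 fell (permutation p of the scan = 0.00899). On chromosome 11, 63 genes from 3125904 to 5838016 had a median of 0.30, and 29 rose and 5 fell (permutation p of the scan = 0.0210). The same scan placed the step on chromosome 16 at 90719312, at Mis18a, with 75 genes and a median of 0.48.

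**Figure D4:**
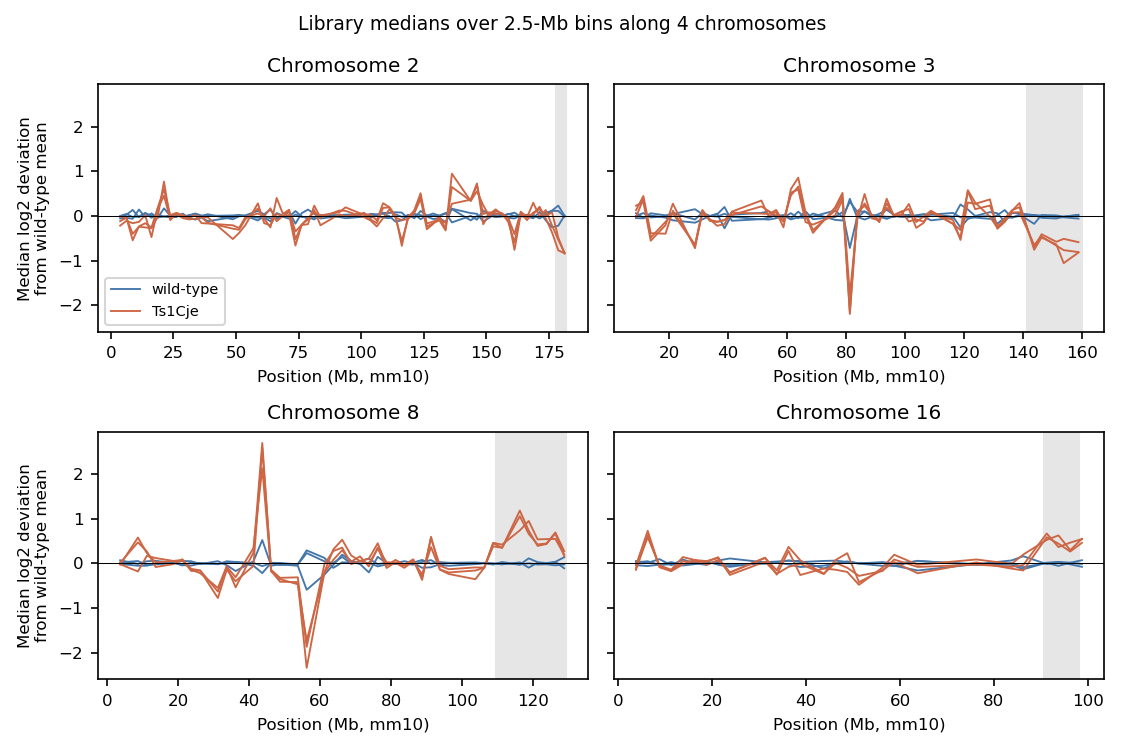
Median log2 deviation from the wild-type mean in 2.5 Mb bins along chromosomes 2, 3, 8 and 16 (position in Mb, mm10), a line for each of 6 libraries, with the located segments shaded. All 3 Ts1Cje lines lie above 0 through the shaded parts of chromosomes 8 and 16 and below 0 at the ends of chromosomes 2 and 3, where segment medians were −0.74 and −0.66.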

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

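No named gene or list that passed its test changed direction under an alternative, and ontology terms and windows were compared only as counts. In contrast, the medians of 7 lists, of which 0 passed camera, changed sign in at least 1 of 15 alternatives. Of the 7579 genes, 0 passed with the opposite sign in any alternative, DESeq2 and limma included; 77.6 to 99.1% of them passed in the same direction. The count of genes was 3128 with a fold change of at least 2, and upper-quartile factors moved the share of higher genes from 53.2 to 49.5%, so that 3802 were higher and 3874 lower. Leaving out each library in turn gave 6039 to 8042 genes, 46 to 52 triplicated genes past the threshold, a segment median of 0.45 to 0.52, 21 to 33 genes that differed from 1.5-fold, a chromosome 12 median of 0.52 to 0.76, 13 to 16 lists, 38 to 69 ontology terms and 9 to 13 windows. The number of genes rose above the full one without wild-type replicate 1 (8042), the wild-type library nearest to Ts1Cje on the first principal component. The cause was not tested. The segment median of 0.48 moved to 0.65 with no filter on low counts, 0.55 with a mean log2 CPM of at least 1, 0.56 over its genes with a mean log2 CPM of at least 3 and 0.55 with limma-trend on log2(TPM + 0.1); the first of these tests more genes and the next 2 fewer. With the estimated correlation, 1 list passed camera in place of 13. Ontology terms were 225 with DESeq2, 144 with no filter, 128 with limma-voom, 86 with log2(TPM + 1) and 87 with log2(TPM + 0.1), against 57, and windows beyond 0.3 were 14 with DESeq2 and 21 with no filter, against 9; the cause was not tested. Leaving out the shifted parts of chromosomes 2, 3 and 8, chosen after seeing the data, gave 7318 genes and 13 lists. Of 152 named genes tested, 131 had the same call in every alternative that tested them. Some alternatives did not test every named gene. In the simulation, genes changed by 1.5-fold were recovered least often. With the replicate number as a block, 8326 genes, 55 triplicated genes, 40 that differed from 1.5-fold, 13 lists, 44 terms and 10 windows were found. The labels do not say that a number pairs samples, and same-numbered libraries deviated together with correlations of 0.22, 0.06 and 0.20; each library correlated best with its own number, a hint from the data and not from the design.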

Other observations

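The genes named next were chosen after their values were seen, so they show no common direction of a group. Foxj1, the master factor of motile cilia, rose from 1.10 ± 0.42 to 34.4 ± 7.03 CPM (log2 fold change 4.95 ± 0.25 SE), the BMP antagonist gene Chrd from 2.22 ± 0.89 to 50.3 ± 9.32 CPM, the cilium sensor gene Pkd1l1 from 0.976 ± 0.546 to 33.5 ± 8.34 CPM, Shh by 5.11 ± 0.77 and the ciliary genes Cfap44 by 4.53 ± 0.39 and Dnah6 by 4.47 ± 0.56. The lysosomal genes Lamp1 (362 ± 42.2 to 737 ± 62.9 CPM), Ctsl (305.5 ± 13.6 to 1140 ± 258 CPM), Ctsb (1.35 ± 0.11) and Atp6v0c (1.02 ± 0.09) rose, as did Lrp2 (2.93 ± 0.34), an endocytic receptor gene of visceral endoderm.

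At the imprinted cluster on distal chromosome 12, the maternally expressed genes Meg3 (log2 fold change 1.32 ± 0.20), Rian (1.08 ± 0.19) and Mirg (1.22 ± 0.18) rose while the paternally expressed Dlk1 (−5.43 ± 0.62) and Rtl1 (−1.10 ± 0.34) fell. Igf2, paternally expressed on chromosome 7, fell as well (−2.45 ± 0.46), and H19 beside it stood at −1.19 ± 0.41 (adjusted p = 0.0693 in edgeR's quasi-likelihood test). Both lie in the segment of chromosome 7 from 142283210 to 145284011, where 23 of 45 genes fell.

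In the 3 patterns weighed next, the tests of GC content and length, of naive-state genes and of other splits were planned before their values were seen, and the remaining tests were chosen after the result was seen.

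The ends of chromosomes 2, 3 and 8 were shifted in all 3 Ts1Cje libraries. A fit on GC content and gene length, which moved other genes by a median of 0.10, left a smallest median of 0.41, past the spread of 0.05 between Ts1Cje libraries, which argues against such a bias as the whole cause. Runs of as many neighbouring genes elsewhere reached such a median in 0% of runs (farthest −0.45, 0.34 and 0.21), but the segments were chosen because they were shifted, so neighbouring genes of the cell state stay open. At least 90.9% of the well-expressed genes of each segment moved in 1 direction (97.9% on chromosome 16), whereas less even segments found by the same scan on chromosomes 7, 14 and 11 reached 77.4, 67.4 and 71.1%. As the scan set the borders on the same values, these shares do not decide on a copy number difference between the lines, in either genotype, which stays open, and genotype and line cannot be separated.

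Dnah11 was 46.0-fold higher in Ts1Cje. Reads shared with other axonemal dynein heavy chain genes are argued against, since all 11 others together held 57.3 ± 4.64 CPM in Ts1Cje, against 753 for Dnah11. An even rise of the motile cilium genes is argued against as the whole cause. The 42 others had a median log2 fold change of 0.73 (quartiles 0.11 and 2.15), and 21 rose and 3 fell. This set also holds broadly expressed genes such as Dync1h1 (0.11, at 750 CPM in Ts1Cje), which lower its median. Single members rose nearly as far as Dnah11, such as Efcab1 (5.32), Cfap52 (4.51) and Enkur (4.08), at 1.71, 2.63 and 2.56 CPM in Ts1Cje. A rise together with part of these genes therefore stays open. Transcription that crosses the chromosome 12 junction could raise Dnah11, but gene counts do not show which exons were joined, and Sp4, the next coding gene toward the chromosome end, at −1.39 does not decide it.

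Mesoderm and vessel genes were lower and epiblast and endoderm genes higher in Ts1Cje. Exchanged labels are argued against, since the lowest Ts1Cje library exceeded the highest wild-type library by 0.45 in the triplicated segment's median. Fibroblasts or feeders in the wild-type cultures are argued against as the source of the higher Hand1 there. Col3a1, Dcn, Lum and Postn together held 0.742 CPM in wild-type, while Hand1 fell by 572 CPM. Of the 11 tested genes of the fibroblast and feeder list, 9 fell and 0 rose in Ts1Cje, and this test does not explain that fall. Undifferentiated stem cells left in Ts1Cje are argued against for the endoderm genes, whose lower quartile was 1.56, but for the pluripotency genes this cannot be told apart from a changed cell state, as 9 naive-state genes went both ways (median 0.94, quartiles 0.10 and 2.20; 4 rose and 1 fell). Genotype and a difference between cell lines both stay open as untested.

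With 10 splits of 6 libraries the share of splits as large as the real one is never under 0.1. All other splits mix the genotypes, so the genotype difference widens the spread within their groups and lowers their counts of genes. Segment genes in them also lack the full dosage difference, so many can differ from 1.5-fold. For these splits the larger count of either direction was taken. Their counts against 1.5-fold are thus no chance level for the real one. The other splits also keep part of the genotype difference, so their counts of lists and terms are no chance level either. The count of lists does not set the real split apart, as 4 of 10 splits, the real one included, gave at least 13. The real split gave 7579 genes in edgeR's quasi-likelihood test (highest other 0, so 1 split as large; at an unadjusted p below 0.05 it gave 8871 and the others 37 to 558), 54 triplicated genes (highest other 0, 1 split as large; unadjusted 56, and 0 or 1 in the others), 38 that differed from 1.5-fold (highest other 30; 1 split), 13 lists (highest other 15; 4 splits) and 57 ontology terms (highest other 36; 1 split).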
